A study of Mus musculus with 2 samples.

How the data were processed

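Gene expression was measured by droplet single-cell RNA sequencing (10x Genomics) of pancreatic tumours from C57BL/6 mice that carry p48-Cre, a conditional deletion of Trp53 on both alleles and an inducible oncogenic Kras allele. The deposit held 2 libraries, 1 control and 1 from ulixertinib, an inhibitor of the kinases ERK1 and ERK2. Per the labels' protocols, 4 mice per group were treated daily by mouth for 14 days, at 100 mg/kg for ulixertinib. The number of mice pooled into each library is not given in the sources used here. The group of each library was taken from its title, since the treatment tag of both libraries reads the same. The treatment protocol names the control as vehicle, and the series' design text names dimethyl sulfoxide.

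The deposited values are unnormalised UMI counts per gene and barcode, and per the file headers the matrices were written by Cell Ranger 7.2.0. Per the labels' protocols, tumours were digested with collagenase, hyaluronidase and DNase. The same protocol names an isolation of nuclei and a 5′ gene expression library, so whether cells or nuclei were loaded stays open, and barcodes are called cells in the text. The submitters' processing notes also list bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, edgeR and the human build GRCh38. These do not match a Cell Ranger matrix of mouse genes, and the mouse reference and annotation release behind the counts are not given in the sources used here. The matrices list 32285 genes by Ensembl mouse identifier and symbol, and counts of identifiers with the same symbol were added up.

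The control library held 7901 barcodes with 37358556 UMIs and the ulixertinib library 8588 barcodes with 43574435 UMIs. The median barcode held 1181 and 1316.5 UMIs, and the lowest 500 in both. Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were retained, which left 4979 and 5813 cells before doublets were called. Doublets were scored per library with the Scrublet method, written out in Python with an assumed rate of 0.06. It called 0 cells of the control library and 2 of the ulixertinib library, 0.0344% of its cells, so the call has not worked. These 2 cells were left out as planned, and alternatives without the highest 6% of scores, or without cells that carried at least 3 markers of each of 2 lineages with at least 2 UMIs each, were added after seeing the data. So were alternatives with named clusters only, with the shares split by sex-linked transcripts, with single clusters, with 5 CPM added before the logarithm, without Gm42418 and AY036118 in the total, and with the epithelial-like cells with Xist, which are under 50 in the control library. The analysis then used 4979 and 5811 cells, with a median of 2592 and 2882 UMIs and of 964 and 1230 genes.

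Counts were scaled to each cell's total and log-transformed. The 2000 most variable genes, without mitochondrial, ribosomal, haemoglobin and sex-linked genes, gave 30 principal components, and cells of both libraries were clustered together by the Leiden method on 15 nearest neighbours at resolution 1. Clusters were named from 17 marker lists fixed before the data were examined, as the class with the highest mean marker fold, and are written as "-like" classes. A cluster stayed unnamed with under 3 detected markers, with a mean marker log2 fold under 1, with a low UMI count and no own marker among its top 10 genes, or with more markers of another class than of its own among these. The scoring rule and its second pass, which set each cluster against those led by another class, were written after the files were seen. No endocrine, erythroid, plasma cell, mast cell or basophil, Schwann cell or adipocyte cluster was named.

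UMIs were summed over the cells of each class in each library and given as counts per 1000000 UMIs of the class (CPM). A gene of a list with under 10 UMIs over both libraries counted as not measured. Each list is described by the median log2 ratio of its measured members (ulixertinib over control, 0.5 counts added), by a 95% interval from 1000 Poisson redraws of the counts, and by the percentile of that median among 10000 random lists matched in size and mean expression. The percentile describes these 2 libraries only. Ratios carry exact conditional binomial 95% intervals, CPM values rest on exact Poisson intervals, shares of cells carry exact Clopper-Pearson 95% intervals, and differences of shares Newcombe intervals. All these intervals cover counting error only, not the spread between animals or between cells, so a gene whose UMIs lie in few cells has an interval that is too narrow. How many cells hold the UMIs of each named gene was counted after seeing the data. A log2 ratio of a gene with no UMI in either library of a subset is 0.00 and measures nothing. With 1 library per group no test between the groups was made, cells were not used as replicates, and no p-value is given. A further log2 ratio, with counts under 3 raised to a floor of 3, was also computed. It is used here only for a second median of the interferon gamma list in epithelial-like cells. The median log2 ratio over all genes with at least 100 UMIs lay between -0.07 and 0.04 in 5 of the 6 classes with lists, and was 0.18 in neutrophil-like cells.

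Before the data were examined, 30 gene lists were fixed that cover MAPK output, interferon responses, antigen presentation, epithelial and mesenchymal programmes, the cell cycle, metabolism, and fibroblast, macrophage, T cell and neutrophil states. Named genes followed a rule fixed at the same time. In epithelial-like cells these are the 10 highest and 10 lowest genes by log2 ratio after adding 5 CPM, among genes with at least 50 CPM in 1 library and 20 UMIs in all. Mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and unnamed gene models were left out, as were genes under 10% of the CPM of the highest other class, where free RNA can give the signal. That last criterion was read in the library with the higher class CPM, against named classes of at least 20 cells. The 3 highest and 3 lowest genes were taken in each other class with at least 100 cells per library. Examples from a list are its most abundant members and the member with the largest difference. Stat1, Isg15 and Spry2 were added as examples after their values were seen. A list of lymph node stroma and high endothelial venule genes was written after clustering, before its genes' values were looked at, and a list of small intestinal enterocyte genes after the cluster led by them was seen.

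Cells were also split by sex-linked transcripts, into those with UMIs of Y-linked genes and no Xist and those with Xist and no Y-linked UMI. Alternatives fixed beforehand were a stricter cell filter (at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs) and no filter, called doublets kept, Leiden resolutions of 0.5 and 2, each library clustered on its own, a denominator without epithelial-like cells, median-of-ratios scaling over genes with at least 100 UMIs, a total without mitochondrial, ribosomal and Malat1 counts, list minimums of 50 and 1 UMIs, cells thinned to 2000 UMIs, a mean over cells, subtraction of free RNA, and, for list medians and genes, the split by sex-linked transcripts with at least 50 cells per library. The free RNA share of a class was estimated from other classes' markers, at 2.65% and 1.68% of UMIs in epithelial-like cells. The GENCODE M21 annotation of the mouse build GRCm38 was used only to find which genes neighbour each other.

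The calculations were checked on simulated counts for the epithelial-like sums over 14116 genes, of which 200 were changed by known folds. The interval held the true ratio for 95.9% of genes. The median recovered log2 ratio was -1.97 for 0.25-fold, -0.99 for 0.5-fold, 1.02 for 2-fold and 2.02 for 4-fold changed genes. Of 200 unchanged lists, 6.50% lay outside the middle 95% of random lists. The simulated counts were independent Poisson draws, as the intervals assume. They held neither UMIs gathered in few cells nor genes that vary together. They therefore check the calculation, not how well the intervals and percentiles hold for these libraries. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.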

Results

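Single-cell transcriptomes were compared between pancreatic tumours of KPPC mice, a Kras-driven and p53-deficient model, given the ERK inhibitor ulixertinib at 100 mg/kg daily for 14 days and tumours of control mice. There was 1 library per group, with 4979 retained cells and 34990915 UMIs in the control library and 5811 cells and 40817883 UMIs in the ulixertinib library. Each group had 4 treated mice, and how many of them each library holds was not stated. The groups therefore had no replicates, no test between them was made, and every difference below is a difference between 2 libraries. Ranges in brackets are 95% intervals for counting error only. No pairing of the libraries is given in the labels.

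The first comparison asked which cell types made up each tumour sample. Neutrophil-like cells made up 17.1% of the control library (16.0 to 18.1, 849 cells) and 3.05% of the ulixertinib library (2.62 to 3.52, 177 cells), a difference of -14.0 percentage points (-15.2 to -12.9). T or NK-like cells made up 4.74% (4.17 to 5.37) and 11.6% (10.8 to 12.5), a difference of 6.88 points (5.86 to 7.89). Of these cells, 179 and 291 belonged to a cluster led by the granzyme Gzma and the chemokine Ccl5. Another 57 and 384 belonged to a cluster led by Lef1 and Themis, genes of naive and maturing T cells. Gzma UMIs lay in only 12 and 71 T or NK-like cells, so most cells of the first cluster held none. At resolution 2 a cluster led by Gzma, Ccl5 and Gzmb held 38 and 106 cells. Clusters led by B cell markers held 2.91% and 14.4% of cells, a difference of 11.5 points (10.4 to 12.5). The larger of them mixed B cell markers with plasma cell immunoglobulin transcripts and was not named.

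Macrophage or monocyte-like cells were the largest named class, at 26.5% (25.3 to 27.8) and 23.8% (22.7 to 24.9), a difference of -2.77 points (-4.41 to -1.12). Epithelial-like cells made up 8.48% (422 cells) and 7.35% (427 cells), a difference of -1.13 points (-2.16 to -0.108). Fibroblast-like cells made up 7.93% and 9.48%, a difference of 1.55 points (0.480 to 2.61). Acinar-like cells were at 4.68% and 1.60%, endothelial-like cells at 2.35% and 3.34%, mesothelial-like cells at 1.02% and 0.447%, dendritic-like cells at 0.723% and 0.620%, and pericyte or smooth muscle-like cells at 0.301% and 0.396%. Unnamed clusters held 25.7% and 34.2% of cells, a difference of 8.46 points that was 0.637 with the 2 called doublets kept and -0.772 with each library clustered on its own. On the latter setting the acinar-like difference of -3.08 points was -0.512. Beside the higher share of lymphoid cells, genes of lymph node stroma and high endothelial venules were 4.53-fold as frequent (3.99 to 5.16) in the ulixertinib library outside the lymphoid clusters. Of the 295 and 1394 UMIs of this list, 61 and 706 were of the gene Glycam1. Its other genes were 1.34-fold to 3.97-fold as frequent, with intervals that included 1 for Chst4 and Cr2. Among cells with Xist, the difference was 3.84 points for neutrophil-like, 0.319 for T or NK-like, 7.31 for epithelial-like and -8.13 for fibroblast-like cells. These were 356 and 683 cells, of which 3 and 32 were neutrophil-like. Another 1754 and 1902 cells had Y-linked UMIs, and the rest of the 4979 and 5811 cells were not assigned. Assigned cells differ from the whole: epithelial-like cells were 17.7% of the control library's cells with Y-linked UMIs, against 8.48% of all its cells. Over named clusters alone the macrophage or monocyte-like difference was 0.392 points.

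**Figure D1:**
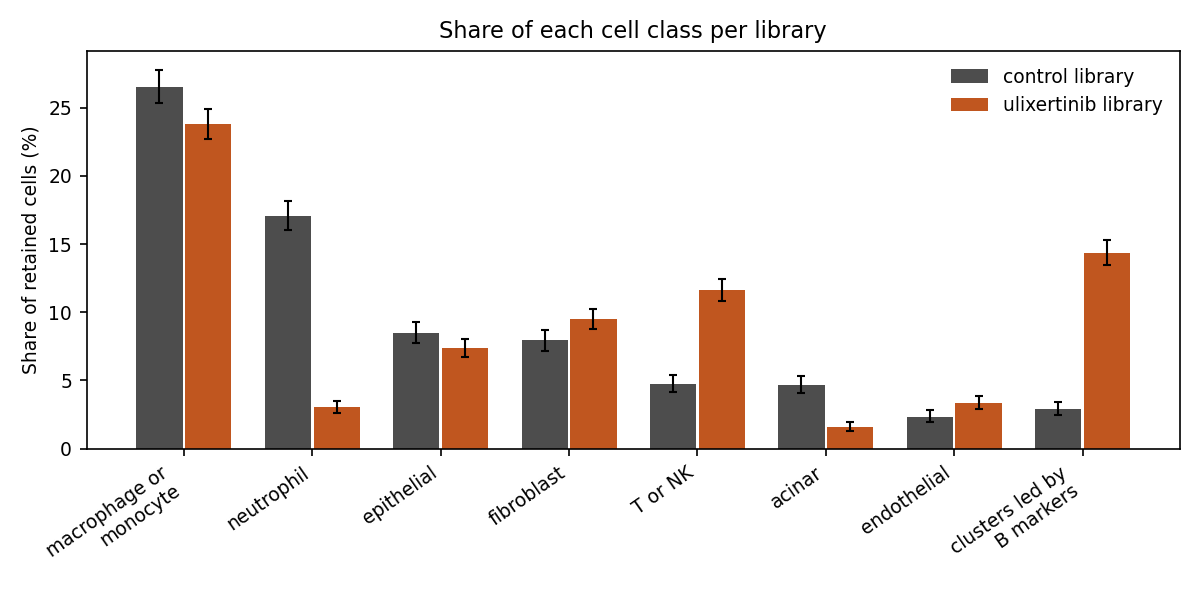
Share of retained cells (%) in 8 cell classes or groups of clusters, for the control library (grey bars) and the ulixertinib library (orange bars), with exact 95% intervals for counting error only. The neutrophil-like share was 17.1% in the control library and 3.05% in the ulixertinib library, and the T or NK-like share 4.74% and 11.6%.

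The series is about interferon signalling and epithelial-to-mesenchymal transition under MAPK inhibition, and the next comparison asked how epithelial-like cells differed in these programmes. Interferon-response genes were higher in the ulixertinib library. Of the 31 measured genes of the type I interferon response, 26 were higher, with a median log2 ratio of 0.85 (0.66 to 1.13), at percentile 100 of random lists. Rsad2, which encodes the antiviral enzyme viperin, had 0.915 and 15.1 counts per 1000000 UMIs of the class (CPM), 16.6-fold higher (8.79 to 35.1). Stat1, the transcription factor activated by interferon receptors, was 2.73-fold higher (2.25 to 3.34), and the ubiquitin-like Isg15 4.51-fold higher (3.58 to 5.73). The most abundant members, the antiviral membrane proteins Ifitm3 and Bst2, went the other way: Ifitm3 was 1.31-fold lower (1.20 to 1.43) and Bst2 1.11-fold lower (0.986 to 1.26, an interval that includes 1).

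Of 16 measured interferon gamma response genes, 15 were higher, with a median of 2.29 (1.70 to 2.48), at percentile 100. The transcription factor Irf1 was 1.71-fold higher (1.52 to 1.93) and the T cell-attracting chemokine Cxcl10 5.005-fold higher (3.64 to 7.01). All 16 genes of MHC class I presentation were higher, with a median of 0.73 (0.52 to 0.85), at percentile 100. Here H2-K1 and B2m, the heavy and light chain genes, were 1.18-fold (1.11 to 1.25) and 1.16-fold (1.09 to 1.24) higher, and the peptide transporter gene Tap1 3.58-fold (2.24 to 5.93). Of 7 MHC class II genes, 6 were higher (median 0.26, 0.17 to 0.45, percentile 96.3), with H2-DMb1 3.64-fold higher (2.04 to 6.90) and Cd74 1.19-fold (1.10 to 1.30). Interferon ligand, receptor and nucleic acid sensing genes had a median of -0.03 (-0.13 to 0.10), with 5 of 11 higher, among them Ifngr1, a chain of the interferon gamma receptor, at 1.57-fold (1.45 to 1.70). The type I median was 0.32 with every cell thinned to 2000 UMIs and 0.43 with 5 CPM added before the logarithm. Its size, though not its sign, thus changed with these settings. Thinning both lowers the counts and gives each cell equal weight. A mean over cells, which gives equal weight without lower counts, put the median between the main and the thinned value, as given below. Equal weight alone thus gave part of the change seen with thinning.

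The direction of the interferon difference was not the same in all cells of the class. Both libraries held cells with Y-linked UMIs and cells with Xist, the RNA of the inactive X chromosome, with 311 and 36 epithelial-like cells of the control library and 257 and 119 of the ulixertinib library. Type I interferon list UMIs in cells with Y-linked UMIs were 301 CPM (290.1 to 313) in the control library and 633 (615 to 652) in the ulixertinib library. In cells with Xist they were 818 (765 to 874) and 245 (230 to 262). The list median was accordingly 1.39 among cells with Y-linked UMIs and -1.65 among cells with Xist. Macrophage or monocyte-like cells and fibroblast-like cells had the same order of these 4 values, while endothelial-like cells had higher values with Xist in both libraries.

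**Figure D2:**
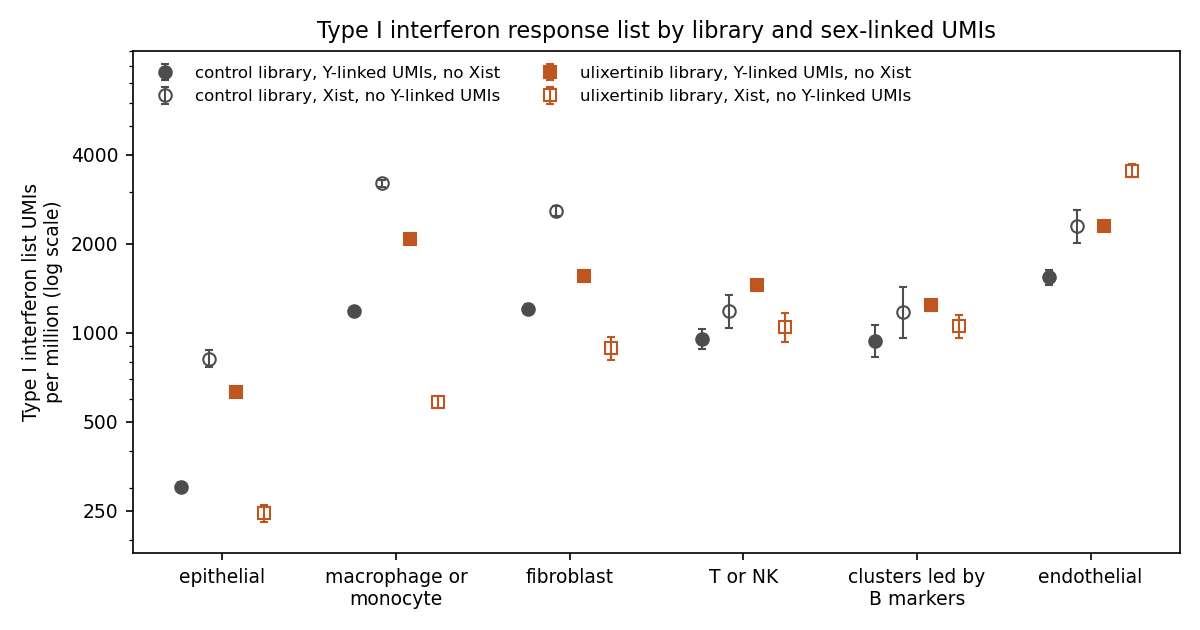
UMIs of the type I interferon response list in CPM (log scale) in 6 cell classes or groups of clusters, for cells with Y-linked UMIs and no Xist (filled symbols) and cells with Xist and no Y-linked UMIs (open symbols) of the control (grey circles) and ulixertinib (orange squares) library, with exact 95% counting intervals. In epithelial-like cells the control library's cells with Xist had 818 CPM and the ulixertinib library's cells with Xist 245.

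Mesenchymal and epithelial genes were both somewhat higher in the epithelial-like cells of the ulixertinib library. Of 23 measured mesenchymal genes, 14 were higher, with a median of 0.22 (-0.02 to 0.44), at percentile 99.6. The intermediate filament Vim was 2.57-fold higher (2.42 to 2.73), the matrix glycoprotein Tnc 2.66-fold (2.48 to 2.85) and fibronectin, Fn1, 1.48-fold (1.45 to 1.52). Of 22 epithelial identity genes, 18 were higher, with a median of 0.10 (0.07 to 0.18), at percentile 96.0. The keratins Krt8, Krt18 and Krt19 were 1.39-fold (1.36 to 1.42), 1.36-fold (1.34 to 1.39) and 1.54-fold higher (1.497 to 1.58). With each library clustered on its own the mesenchymal median was 0.48. Among cells with Y-linked UMIs the epithelial identity median was 0.03, and among cells with Xist 0.38.

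Genes of the classical, gastric-like subtype of pancreatic cancer differed more. Of 16 measured genes, 14 were higher in the ulixertinib library, with a median of 0.54 (0.50 to 0.62), at percentile 100. The trefoil factors Tff1 and Tff2 were 4.57-fold (4.46 to 4.68) and 2.95-fold higher (2.89 to 3.01), and the gastric mucin Muc5ac 9.31-fold (7.60 to 11.5). The list's UMIs were higher both in cells with Y-linked UMIs, at 4085 and 11532 CPM, and in cells with Xist, at 5054 and 11823. They were also higher in other classes, at 48.9 and 253 CPM in macrophage or monocyte-like and 64.9 and 274 CPM in fibroblast-like cells with Y-linked UMIs. After subtraction of free RNA the epithelial-like median was 0.53. The subtracted profile came from the library's other cells, where these transcripts were rarer, so this median could hardly change whatever their source. Basal-like genes had a median of 0.28 (-0.05 to 0.41), at percentile 97.4, with 5 of 8 higher. Of these, Ly6d was 2.32-fold higher (2.12 to 2.53), and the more abundant Hmga2, a chromatin protein, 1.26-fold lower (1.22 to 1.30).

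**Figure D3:**
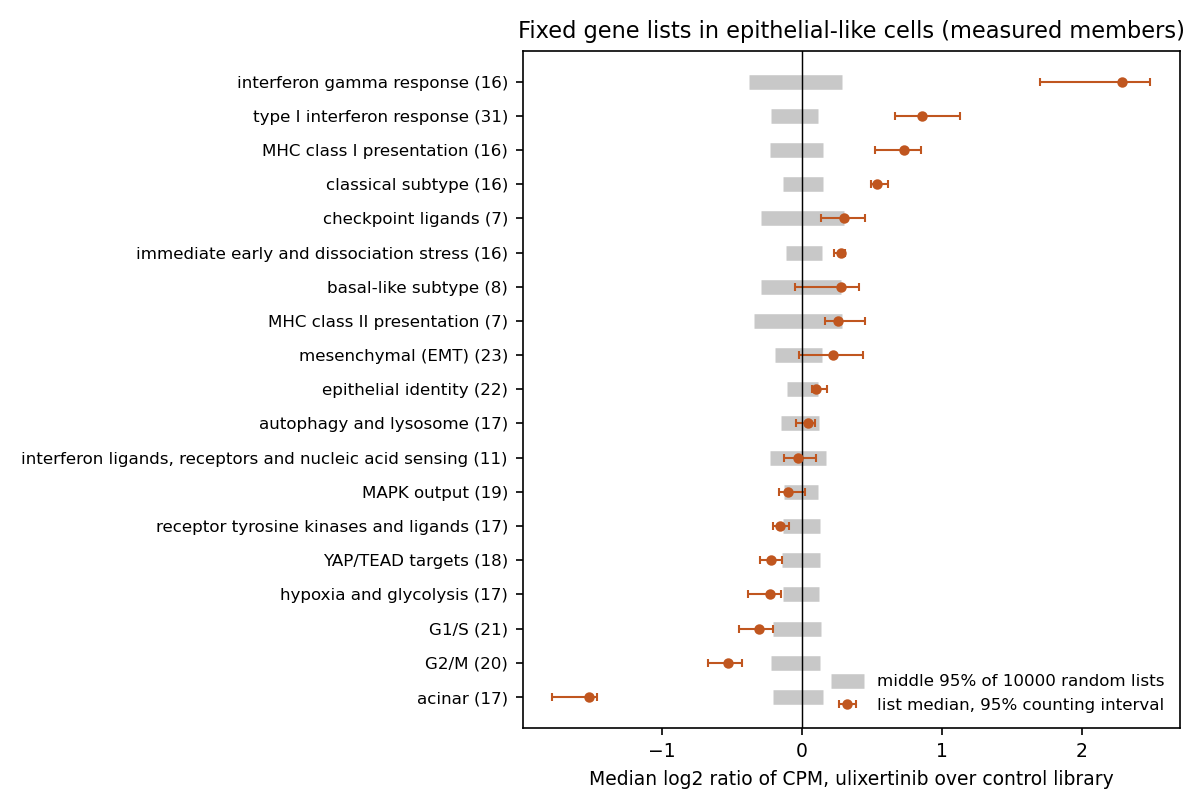
Median log2 ratio of CPM (ulixertinib over control library) of 19 gene lists in epithelial-like cells, with the number of measured genes in brackets. Points and lines give the median and its 95% counting interval, and grey bars the middle 95% of 10000 random lists matched on expression. The interferon gamma list lies highest, at 2.29, and the acinar list lowest, at -1.52.

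Target genes of the inhibited pathway were close to even between the libraries. Of 19 measured MAPK output genes, 8 were higher and 11 lower, with a median of -0.10 (-0.17 to 0.02), at percentile 6.63. The ephrin receptor Epha4 was 2.74-fold lower (2.48 to 3.03) and the feedback inhibitor Spry2 1.95-fold lower (1.66 to 2.29). The most abundant members were higher, Ier3 1.37-fold (1.32 to 1.43) and Emp1 1.14-fold (1.11 to 1.18). The sign of the median was not stable: it was 0.12 with cells thinned to 2000 UMIs and 0.16 without the highest 6% of doublet scores.

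Proliferation genes were lower in the epithelial-like cells of the ulixertinib library. Of 20 measured G2/M genes, 19 were lower, with a median of -0.53 (-0.67 to -0.43), at percentile 0. The chromatin protein Hmgb2 was 1.65-fold lower (1.54 to 1.76) and the ubiquitin-conjugating enzyme Ube2c, which acts at mitotic exit, 1.52-fold lower (1.33 to 1.74). Of 21 G1/S genes, 18 were lower, with a median of -0.31 (-0.45 to -0.21), at percentile 0.15, among them the histone mRNA-binding protein Slbp, 1.45-fold lower (1.28 to 1.64). The G2/M median was -0.23 without the highest 6% of doublet scores and -1.58 among cells with Xist.

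Hypoxia and glycolysis genes were all lower, 17 of 17, with a median of -0.23 (-0.39 to -0.15), at percentile 0.11. The mitophagy receptor Bnip3 was 2.29-fold lower (1.964 to 2.68) and the pyruvate kinase Pkm 1.09-fold lower (1.05 to 1.14). YAP/TEAD target genes had a median of -0.22 (-0.30 to -0.14), at percentile 0.18, with 14 of 18 lower, among them Ankrd1, 2.23-fold (1.997 to 2.501), and Ccn2, 1.20-fold (1.14 to 1.26). Receptor tyrosine kinase and ligand genes had a median of -0.16 (-0.21 to -0.09), at percentile 1.07, with 11 of 17 lower, among them the ligand Nrg1, 4.33-fold (3.51 to 5.37). In the smaller group of cells with Xist the hypoxia median was 0.86 and the receptor median 0.19, and the receptor median was 0.01 after thinning.

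Of the remaining lists in these cells, immediate early and dissociation stress genes had a median of 0.28 (0.23 to 0.31), at percentile 99.99, with Fos 1.54-fold higher (1.4997 to 1.58) and the heat shock gene Hspa1b 1.55-fold lower (1.48 to 1.63). All 7 measured checkpoint ligand genes were higher (median 0.30, 0.14 to 0.45, percentile 97.6), among them Lgals9 at 1.36-fold (1.24 to 1.499). Autophagy and lysosome genes had a median of 0.04 (-0.04 to 0.09), at percentile 79.1. Acinar genes had a median of -1.52 (-1.78 to -1.46), at percentile 0, with the chymotrypsinogen Ctrb1 3.35-fold lower (3.24 to 3.46), beside an acinar-like share of cells of 4.68% in the control and 1.60% in the ulixertinib library. With each library clustered on its own these shares were 2.61% and 2.10% and the acinar list median was -2.74, and among cells with Y-linked UMIs that median was -0.58.

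By the size rule, the 10 genes highest in the ulixertinib library's epithelial-like cells included the gastrokines Gkn1, Gkn2 and Gkn3, the mucins Muc5ac and Muc6, Tff1 and pepsinogen C (Pgc). Gkn2 had 41.9 and 526 CPM, 12.6-fold higher (11.4 to 13.8), and Muc6 124 and 1220 CPM, 9.87-fold higher (9.33 to 10.4). The others were Mucl3, Ptprn2 and Pvt1, a non-coding RNA gene next to Myc, which was 5.21-fold higher (4.82 to 5.65). The log2 ratio of these 10 genes, with 5 CPM added, ranged from 1.95 to 3.50. Single cells held much of some of these counts, with 37.1% and 36.9% of the Gkn2 UMIs, 52.6% and 43.4% of the Gkn1 UMIs and 19.0% and 36.8% of the Muc6 UMIs in the highest cell of each library. Of the 458 and 6221 Gkn2 UMIs, 413 and 1116 lay in cells with Y-linked UMIs, and of the 2450 and 11826 Gkn1 UMIs, 2308 and 2280. Much of the difference of these 2 genes thus lay in other cells. Muc6 had 1188 and 13749 UMIs in cells with Y-linked UMIs, of 1351 and 14416. The lowest genes were the protocadherin Pcdh7, 7.05-fold lower (6.32 to 7.88), Prkg2, 4.39-fold lower (3.79 to 5.11), Klhl1, Mcpt8, Epha4, Cxcl5, Prxl2a, Myo3b, Ankrd1 and Antxr2, with log2 ratios from -2.64 to -0.91. Among cells with Xist, 8 of these 10 were higher in the ulixertinib library, all but Ankrd1 and Antxr2. Mcpt8, a basophil protease gene, was also at 99.01 and 7.37 CPM in the unnamed clusters.

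Over all macrophage or monocyte-like cells, interferon genes did not show the difference seen over all epithelial-like cells. Split by sex marker, the type I list had the same signs in both classes. Of 31 measured type I interferon genes, 10 were higher and 21 lower, with a median of -0.14 (-0.22 to -0.06), at percentile 0.705. Oasl1 was 2.17-fold lower (1.64 to 2.88), and the abundant Ifitm3 1.09-fold lower (1.06 to 1.13) and Bst2 1.25-fold higher (1.16 to 1.35). This median was 0.68 among cells with Y-linked UMIs and -2.06 among cells with Xist, and it ranged from -0.58 to 0.22 over the 4 clusters of the class. Interferon gamma response genes had a median of -0.02 (-0.19 to 0.17) and MHC class I genes of 0.10 (0.03 to 0.20), at percentiles 37.8 and 88.4.

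Heat shock and immediate early genes were lower in these macrophages, with 13 of 16 lower and a median of -0.34 (-0.39 to -0.30), at percentile 0. The heat shock genes Hspa1a and Hspa1b were 5.64-fold (5.31 to 5.99) and 7.18-fold lower (6.70 to 7.71). In the low-UMI cluster of the class alone the median was 0.30. MAPK output genes had a median of -0.22 (-0.30 to 0.03), at percentile 0.26, with Epha4 4.10-fold lower (2.75 to 6.28). Of the suppressive macrophage genes 9 of 14 were lower (median -0.12, -0.17 to -0.09, percentile 0.75). Among them Retnla, a marker of alternatively activated macrophages, was 10.1-fold lower (9.50 to 10.7), while the abundant Chil3 was 1.10-fold lower (1.09 to 1.12) and Arg1 1.10-fold higher (1.07 to 1.12). Of the 12959 and 1268 Retnla UMIs, 3699 and 967 lay in cells with Y-linked UMIs, where the gene was also lower, but by less. Inflammatory macrophage genes had a median of -0.08 (-0.14 to -0.05), at percentile 9.70, with nitric oxide synthase, Nos2, 5.99-fold lower (3.31 to 11.7) and Il1b 1.11-fold higher (1.09 to 1.14).

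MHC class II genes were higher in 6 of 7 cases in macrophages (median 0.20, 0.17 to 0.24, percentile 97.2), with Cd74 1.18-fold higher (1.16 to 1.19). Checkpoint ligand genes had a median of 0.15 (0.03 to 0.25), at percentile 91.3, with Cd80 1.54-fold higher (1.45 to 1.65), and hypoxia genes of -0.06 (-0.13 to 0.01), at percentile 6.04. By the size rule the highest genes were Lepr, the leptin receptor, 2.42-fold (2.24 to 2.62), Wfdc21 and Gpr171, and the lowest were Retnla, Hspa1b and Hspa1a. Lepr and Wfdc21 were lower among cells with Y-linked UMIs, with log2 ratios of -1.57 and -0.94. A cluster led by Chil3 and Arg1 had 159 cells with Y-linked UMIs and 1 with Xist in the control library, and 31 and 144 in the ulixertinib library.

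Fibroblast-like cells of the ulixertinib library had higher levels of contractile, matrix and inflammatory genes. Of 14 myofibroblastic genes, 11 were higher, with a median of 0.48 (0.44 to 0.54), at percentile 100, with smooth muscle actin, Acta2, 3.01-fold higher (2.82 to 3.21) and Igfbp3 1.44-fold (1.395 to 1.49). Collagen and matrix genes had a median of 0.37 (0.35 to 0.38), at percentile 99.96, with 11 of 14 higher, among them the collagens Col1a1, 1.29-fold (1.27 to 1.31), and Col3a1, 1.34-fold (1.31 to 1.36), and the collagen cross-linking enzyme Lox, 1.65-fold (1.55 to 1.75). Inflammatory fibroblast genes had a median of 0.37 (0.25 to 0.44), at percentile 100, with 13 of 16 higher. The neutrophil-attracting chemokine Cxcl1 was 2.35-fold higher (2.05 to 2.69) and complement C3 1.53-fold (1.47 to 1.59).

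MAPK output genes were lower in fibroblasts, with 13 of 19 lower and a median of -0.31 (-0.41 to -0.11), at percentile 0.25. The feedback inhibitor Spry4 was 2.41-fold lower (1.75 to 3.33) and Emp1 1.49-fold lower (1.402 to 1.59). As a mean over cells this median was 0.01. Type I interferon and MHC class I genes had medians of 0.04 (-0.15 to 0.14) and -0.01 (-0.13 to 0.18), at percentiles 93.4 and 71.4. Immediate early and dissociation stress genes had a median of -0.14 (-0.19 to -0.11), at percentile 1.38. By the size rule Muc6, smooth muscle Actg2, 11.6-fold (7.66 to 18.3), and the acute phase gene Saa3, 3.87-fold (3.58 to 4.17), were highest, and the imprinted gene Mest, 11.3-fold (8.18 to 16.1), Ptn and Syne3 lowest. Muc6 reached 413 CPM here and 1220 CPM in epithelial-like cells of the same library. Of the lowest genes, Mest had 52 and 34 UMIs in cells with Y-linked UMIs, Ptn 461 and 473, and Syne3 81 and 48. In the whole class they had 326 and 41, 1437 and 609, and 201 and 70 UMIs, so much of these differences lay in other cells. A cluster of low UMI count held 186 and 341 of the fibroblast-like cells.

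T or NK-like cells of the ulixertinib library had more naive and fewer regulatory T cell transcripts. Of 7 naive T cell genes, 6 were higher, with a median of 1.19 (0.92 to 1.43), at percentile 100, with the lymph node homing receptor Ccr7 3.64-fold higher (2.96 to 4.53) and the transcription factor Lef1 3.25-fold (2.91 to 3.63). All 6 regulatory T cell genes were lower, with a median of -0.90 (-1.08 to -0.70), at percentile 0, with the interleukin-2 receptor chain Il2ra 2.86-fold lower (2.36 to 3.46) and Ikzf2 1.37-fold (1.26 to 1.49). The cluster led by Gzma and Ccl5 held most of these cells in the control library and that led by Lef1 and Themis in the ulixertinib library. Within each of them the naive list median was 0.21 and 0.23 and the regulatory median -0.25 and -0.41.

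Effector genes had a median of 0.23 (-0.10 to 0.47), at percentile 92.7, with 7 of 11 higher. The granzymes Gzma and Gzmb were 5.88-fold (5.25 to 6.60) and 4.76-fold higher (3.81 to 6.01), and the chemokine Ccl5 2.37-fold (2.22 to 2.53). T cell checkpoint genes had a median of 0.15 (-0.15 to 0.30), at percentile 74.4, with Lag3 5.37-fold higher (2.20 to 17.1). Type I interferon genes had a median of 0.28 (0.09 to 0.49), at percentile 98.4, with Stat1 1.94-fold higher (1.66 to 2.27). Immediate early and dissociation stress genes had a median of -0.41 (-0.49 to -0.35), at percentile 0.02. MHC class I genes had a median of -0.08 (-0.13 to 0.05) and MAPK output genes of -0.04 (-0.31 to 0.33), at percentiles 17.5 and 36.4. By the size rule Tff2, Gzma and Gzmb were highest and Il17a, the cytokine of type 17 T cells, at 10.1-fold (7.52 to 13.8), Pde7b and Klrg1 lowest. Gzma UMIs lay in 12 and 71 cells and Il17a UMIs in 16 and 11 cells. Tff2 reached 401 CPM here and 3680 CPM in epithelial-like cells of the same library.

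Neutrophil-like cells of the ulixertinib library had lower levels of interferon genes, while genes of late tumour neutrophils were split. Of 30 type I interferon genes, 28 were lower, with a median of -1.19 (-1.63 to -1.06), at percentile 0, and Rsad2 was 33.1-fold lower (16.8 to 77.0). Of 9 late tumour neutrophil genes, 5 were lower and 4 higher, with a median of -0.75 (-0.97 to -0.56), at percentile 0.62. The chemokines Cxcl3 and Ccl3 were 5.38-fold (4.68 to 6.21) and 2.77-fold lower (2.57 to 2.99), and Siglecf, Il23a, Ptgs2 and Vegfa, named after their values were seen, were 2.05-fold (1.59 to 2.62), 1.74-fold (1.43 to 2.11), 1.37-fold (1.23 to 1.52) and 1.32-fold higher (1.13 to 1.54). Early neutrophil genes had a median of 0.34 (0.25 to 0.48), at percentile 80.3, with Retnlg 1.91-fold higher (1.76 to 2.07). One cluster held 555 of the control library's 849 cells and the other 145 of the ulixertinib library's 177 cells, and within the latter cluster the type I interferon median was 0.18 and the late neutrophil median -0.17.

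Other lists in neutrophil-like cells had medians of 0.16 (-0.10 to 0.40) for MHC class I and 0.10 (-0.28 to 0.32) for MAPK output, both at percentile 23.4. Immediate early and dissociation stress genes were at -0.19 (-0.28 to 0.02), at percentile 10.8. By the size rule Arpp21, with 3 and 35 UMIs, Maml2, 9.87-fold (7.79 to 12.6), and St6galnac3 were highest, and Rsad2, Prss34 and Prok2, which had 297 and 2 UMIs, lowest. The basophil protease gene Prss34 had 235 UMIs and 0 UMIs, and all 235 lay in 1 cell. The UMIs of Arpp21 lay in 1 and 2 cells and those of St6galnac3 in 4 and 3 cells, so these 3 genes describe a few cells and not the class. With each library clustered on its own the log2 ratio of Arpp21 was -0.36. Among cells with Y-linked UMIs St6galnac3 was at -0.97, and Prss34 had no UMI in either library.

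Endothelial-like cells of the ulixertinib library had higher interferon and antigen presentation genes. Of 26 type I interferon genes, 21 were higher, with a median of 0.43 (0.31 to 0.65), at percentile 100, with Ifitm3 1.43-fold (1.32 to 1.54) and Ifit2 6.75-fold higher (2.97 to 18.9). MHC class I genes had a median of 0.44 (0.32 to 0.56), at percentile 100, with 13 of 16 higher, among them B2m at 1.32-fold (1.21 to 1.44). Immediate early and dissociation stress genes had a median of 0.46 (0.37 to 0.53) and MAPK output genes of 0.08 (-0.07 to 0.29), at percentiles 100 and 70.1. Without cells that carried markers of 2 lineages, 8 of 117 and 22 of 194 cells, these medians were 0.08, 0.13, 0.21 and -0.12. Over all cells of the class, 11 of the 16 stress list genes were higher, among them Jun at 1.63-fold (1.52 to 1.76), and 5 were lower, among them Hspa1b at 3.06-fold (2.74 to 3.42). By the size rule Nxph1, Trpc6 and Pde3a were highest, with 1, 2 and 6 UMIs in the control library and 169, 167 and 242 in the ulixertinib library, and Chrm2, Hspa1b and Nt5e lowest. The ulixertinib library's UMIs of the highest genes lay in 3, 9 and 8 cells, and 162 of the 169 Nxph1 UMIs in 1 cell. Without the cells of 2 lineages the log2 ratios of Trpc6 and Pde3a, genes that also lead the pericyte cluster, were 0.74 and 0.32 in place of 3.65 and 3.52.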

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

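Of the tests below, those of an interferon state shared by an animal's cell types, of lymph node tissue, of an extra copy on chromosome 15 and of regulation shared by all cell types were chosen before their values were seen. All the others were chosen after the result they concern was seen. None of the differences named here was tested between groups.

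The interferon and antigen presentation lists were checked for opposite signs in cells with Xist and cells with Y-linked UMIs, and had them. Other lists were not checked by this rule, so the pattern is not shown to be particular to interferon. In epithelial-like cells with Xist, the hypoxia, receptor, checkpoint ligand and MAPK output medians and most of the lowest named genes also changed sign, as given below. In epithelial-like cells the median log2 ratio of the type I interferon list was -1.65 with Xist and 1.39 with Y-linked UMIs. The MHC class I list was at -1.88 and 1.08, and the interferon gamma list at -1.15 and 2.47. In macrophage or monocyte-like cells the type I list was at -2.06 and 0.68. The group with Xist held only 36 epithelial-like cells in the control library. Another result was flagged as data left unanalysed: an unnamed cluster led by intestinal genes held 126 cells of the ulixertinib library and 2 of the control library.

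Free RNA does not explain the higher type I interferon list in epithelial-like cells, since the median was 0.98 after subtraction. Cells with markers of 2 lineages do not either, since it was 0.76 without these 25 control and 35 ulixertinib cells. Capture with cells that add few UMIs can escape that rule and is not excluded. The highest 6% of doublet scores held 51 control and 95 ulixertinib epithelial-like cells, and leaving such scores out lowered the median, as given below. A larger share of cells with Xist would not give the higher list, since its median was 1.39 within cells with Y-linked UMIs. An interferon state that differs between animals could give opposite signs by sex marker, and in clusters led by B markers the same contrast was -0.56 (-0.914 to -0.203), which has the same sign but stayed short of the value set beforehand. The contrast was -3.26 in macrophage or monocyte-like, -1.91 in fibroblast-like and -0.79 in T or NK-like cells. It was 0.04 (-0.168 to 0.266) in endothelial-like cells, with 11 control cells with Xist, and 0.03 (-0.780 to 0.995) in neutrophil-like cells, with 3. The endothelial-like and neutrophil-like values rest on few cells, and their intervals cover counting error only. Cells with markers of 2 lineages were also kept in them. They cannot decide whether a state was shared by all cell types, and a state shared by some stays open. What the drug adds to differences between animals cannot be read from 1 library per group.

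The higher T or NK-like and lower neutrophil-like shares were weighed next. Lymph node tissue in the ulixertinib sample may account for part of the lymphoid cells, since lymph node stroma genes were 4.53-fold as frequent there outside the lymphoid clusters. Which lymphoid tissue gave these transcripts, and whether it lay within the tumour, was not tested. Dilution by it does not account for the neutrophil-like share, which differed by -14.35 points outside the lymphoid clusters. A larger share of cells with Xist does not account for it either among assigned cells, at -17.85 points within the 1754 and 1902 cells with Y-linked UMIs. Only 0.824% of the control library's sex-assigned neutrophil-like cells had Xist (0.170 to 2.39), against 20.2% of its other cells (18.4 to 22.2) and 38.1% of the ulixertinib library's neutrophil-like cells, so they may come from part of its animals; this contrast was seen before it was tested and Xist separates sexes, not animals, which leaves it open.

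Pvt1, Fam49b and Asap1, neighbours on chromosome 15, were higher together in epithelial-like cells, with log2 ratios of 2.38, 1.25 and 1.095. With Gsdmc4 (1.63) and Adcy8 (0.70) they form an unbroken run that ranked 2 of 11701 runs of 5 genes by its lowest member, and they were at 2.61, 1.63 and 1.35 in cells with Y-linked UMIs against 0.44, -0.0843 and 0.48 with Xist. An extra copy of this stretch could give this, but it stays open, since the neighbours' median lay at percentile 85.2 of windows of 10 genes, between the bounds set beforehand, and the run was seen afterwards. Regulation shared by all cell types does not explain it, since the higher of the medians in macrophage or monocyte-like and fibroblast-like cells was -0.0188. Regulation shared with some types is not excluded: Pvt1 was 1.86-fold higher in endothelial-like (1.32 to 2.67) and 1.29-fold in macrophage or monocyte-like cells (1.18 to 1.41), Fam49b and Asap1 were at 0.65 and 0.93 in neutrophil-like cells, and Asap1 was 2.07-fold higher in T or NK-like cells.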

How the results depend on the processing

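No paired analysis was possible because the labels give no pairing of the libraries and each group has 1 library. For the main list medians 129 of 137 alternative values had the same sign, for other list medians 860 of 932, for named genes 763 of 776, and for shares 55 of 59 main and 33 of 35 other values. Shares moved as follows, in percentage points. The neutrophil-like difference of -14.0 became -17.7 with the stricter filter, -9.38 with no filter, -15.3 without the epithelial-like class in the denominator, -17.85 in cells with Y-linked UMIs, 3.84 in cells with Xist (reversed) and -18.3 over named clusters. The T or NK-like difference of 6.88 became 9.54 with the stricter filter, 4.91 with no filter, 11.45 with Y-linked UMIs, 0.319 with Xist and 11.3 over named clusters. The unnamed difference of 8.46 became -1.65 with the stricter filter and -0.772 with each library clustered on its own, both reversed. It became 0.637 with called doublets kept, 1.71 at resolution 2, 6.07 at resolution 0.5, 6.22 with no filter and 10.8 with Xist. The acinar-like difference of -3.08 became -1.72 with the stricter filter, -4.82 with no filter, -1.22 at resolution 0.5, -0.512 clustered on its own, -0.658 with Y-linked UMIs, -0.977 with Xist and -3.87 over named clusters. The macrophage or monocyte-like difference of -2.77 became -0.569 clustered on its own, -6.54 with Y-linked UMIs, -13.99 with Xist and 0.392 over named clusters (reversed). With the stricter filter it was -4.35 and with no filter -1.36. The epithelial-like difference of -1.13 became -0.652 with the stricter filter, -0.384 with no filter, -0.245 over named clusters, -1.85 without the highest doublet scores, -4.22 with Y-linked UMIs and 7.31 with Xist (reversed). The fibroblast-like difference of 1.55 became 0.626 with the stricter filter, 0.984 at resolution 2, -8.13 with Xist (reversed) and 3.73 over named clusters. The endothelial-like difference of 0.989 became 1.91 over named clusters. In epithelial-like cells, the type I interferon median of 0.85 became 0.32 thinned, 0.60 as a mean over cells, 1.39 with Y-linked UMIs, -1.65 with Xist (reversed), 0.62 without the highest doublet scores and 0.43 with 5 CPM added. MHC class I, at 0.73, became 0.25 thinned, 1.08 with Y-linked UMIs, -1.88 with Xist (reversed), 0.39 without the highest doublet scores and 0.48 with 5 CPM added. MAPK output, at -0.10, became 0.12 thinned, 0.50 with Xist and 0.16 without the highest doublet scores. G2/M, at -0.53, became -0.36 with Y-linked UMIs, -1.58 with Xist, -0.23 without the highest doublet scores and -0.40 with 5 CPM added. The receptor list, at -0.16, became 0.00664 thinned and 0.19 with Xist, both reversed. Epithelial identity, at 0.10, became 0.0325 with Y-linked UMIs and 0.38 with Xist, and the mesenchymal list, at 0.22, became 0.48 clustered on its own. With Xist, the interferon gamma list reversed to -1.15, hypoxia to 0.86 and checkpoint ligands to -0.14, as did Pcdh7 (1.29), Prkg2 (1.71), Klhl1 (3.47), Mcpt8 (2.37), Epha4 (0.0862), Cxcl5 (0.77), Prxl2a (1.11) and Myo3b (0.0659). In macrophage or monocyte-like cells, the type I interferon median of -0.14 became -0.24 thinned, -0.0231 as a mean over cells, 0.68 with Y-linked UMIs (reversed), -2.06 with Xist and -0.0257 without the highest doublet scores. By cluster it was -0.29 in cluster 1, 0.0685 in cluster 5, -0.58 in cluster 8 and 0.22 in cluster 13. The suppressive list, at -0.12, reversed to 0.35 with Xist, 0.17 in cluster 1, 0.0467 in cluster 5 and 0.0104 in cluster 8. The immediate early and dissociation stress list, at -0.34, reversed to 0.30 in cluster 1. With Y-linked UMIs Lepr reversed to -1.57, Wfdc21 to -0.94 and St6galnac3 to -0.97, and Prss34 was at 0.00 because no UMI was found in either library. Arpp21 in neutrophil-like cells reversed to -0.36 with each library clustered on its own, and their type I interferon median to 0.18 in cluster 11. MAPK output in fibroblast-like cells, at -0.31, became 0.0109 as a mean over cells. Medians within cells with Xist were not run as planned where a library had under 50 such cells, and for epithelial-like cells they were added later. Keeping called doublets added back 2 cells, and the new clustering split the larger cluster led by B markers into a B-like and a plasma-like one, which moved the unnamed share. The settings added after seeing the data were the single clusters, named clusters only, the highest doublet scores left out, cells with markers of 2 lineages left out, the total without Gm42418 and AY036118, 5 CPM added, the epithelial-like cells with Xist, and for shares both sex marker groups. The split by sex marker was planned for list medians and genes. The cause was not tested.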

Other observations

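Several genes known from the stomach lining were among the genes highest by size in the epithelial-like cells of the ulixertinib library. The gastrokines Gkn1 and Gkn3 were at 224 and 508 CPM in the control and 1001 and 1971 CPM in the ulixertinib library, and pepsinogen C, Pgc, at 7.41 and 56.0 CPM. However, the highest single cell of each library held 52.6% and 43.4% of the Gkn1 UMIs. In cells with Y-linked UMIs Gkn1 had 2308 UMIs in the control and 2280 in the ulixertinib library. Most of the ulixertinib library's 11826 Gkn1 UMIs thus lay in other cells. Gkn3 had 4267 and 11805 UMIs and Pgc 70 and 389 UMIs in cells with Y-linked UMIs. No list of gastric genes was fixed, so no wider programme was measured beyond the classical list. That list had a higher frequency in both sex marker groups of epithelial-like cells, at 4085 and 11532 CPM with Y-linked UMIs and at 5054 and 11823 CPM with Xist, unlike the interferon lists.

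The classical list was also higher outside the epithelial-like class, at 48.9 and 253 CPM in macrophage or monocyte-like cells, 64.9 and 274 CPM in fibroblast-like cells and 147 and 788 CPM in clusters led by B markers, each with Y-linked UMIs. Muc6 was at 7.86 and 326 CPM in the unnamed clusters. Free RNA may carry these transcripts into other cells. Subtracting free RNA left the epithelial-like median at 0.53 against 0.54. The subtracted profile came from the other cells, where these transcripts were rarer. That median could therefore hardly change and does not show where the transcripts came from. Whether all of the transcripts come from tumour cells was not tested.

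An unnamed cluster, found almost only in the ulixertinib library, was led by genes of small intestinal enterocytes, with 2 and 126 cells. Over the whole libraries the brush border phosphatase Alpi had 2 and 1613 UMIs. Outside the lymphoid clusters the lymph node venule mucin Glycam1 had 61 and 706 UMIs and the chemokine Ccl21a 141 and 427 UMIs. The lymph node list, 4.53-fold as frequent there, may come from tissue taken along with the tumour, but its source was not tested. An enterocyte list, written after the intestinal cluster was seen and holding its leading genes, was 7.02-fold as frequent (6.74 to 7.32) over the whole ulixertinib library, which restates the cluster and is no test of where it comes from.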
